A study of Drosophila melanogaster with 6 samples.

How the data were processed

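Messenger RNA was sequenced from ovaries of Drosophila melanogaster females aged 3 to 6 days, as 6 libraries in 2 groups of 3. One group was homozygous for flamDeltaProm, a deletion of the promoter of flamenco (flam), the X-linked locus that gives rise to piRNAs against transposons in the somatic follicle cells. The other group carried flamDeltaProm over the balancer chromosome FM7. The titles of these controls name a wild-type chromosome, whereas their genotype field names FM7, and the genotype field was followed. The series text also mentions ovaries with a somatic knockdown of traffic jam, and these were not analysed here. The labels do not say whether replicates were separate pools of animals, so p-values measure the spread between these samples, which may be technical.

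RNA was extracted with TRIzol and made into strand-specific polyA libraries, per the labels' protocols. The deposited table holds whole-number counts of reads per gene or transposon family, not normalised. STAR 2.7.8a, featureCounts 2.0.1 and DESeq2 1.30.1 are named without roles or settings, per the submitters' processing notes. The genome build, the annotation release, the handling of reads that map to several places and the way transposon families were counted are not given in the sources used here. Reads shared by closely related families, or by near-identical gene copies such as those of Hsp70, may therefore be split or assigned in ways that cannot be seen in the counts. Of genes with at least 50 counts in total, 166 fell into 79 sets with identical counts, and all 79 sets were genes overlapping on the same strand, so such reads were counted for each overlapping gene. Of the genes named below, Rel, Vago, qin, fit, Pxn, srp, Hr3, Hr39, Msp300, Glut4EF, Abca3, Gr64d and Gr64e overlap another gene on the same strand without identical counts, and their values may hold some of its reads. Whether the counting used strand is not given in the sources used here, so reads of antisense neighbours may be mixed too.

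The table lists 17633 genes and 127 transposon families. Symbols and positions were looked up by gene identifier in Ensembl release 115, assembly BDGP6.54, and 35 identifiers, which took 0.0153% to 0.0177% of the counts of a library, had no match. Positions below are those of BDGP6.54, which may not be the build the authors used. Library totals ran from 19564819 to 23181058 counts, and 3 counts, the floor used for genes without a count, correspond to 0.129 to 0.153 CPM (counts scaled to library size) in a library. The exact intervals of count ratios and the floors cover counting error only, and reads amplified by PCR are not independent molecules. Intervals of folds fitted by edgeR use the spread between libraries, and those of odds ratios and bootstraps run over genes. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 8.18 to 38.9 between any pair, so each was counted as a sample.

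Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter by group (filterByExpr) and the robust quasi-likelihood test. The filter kept 9150 genes and 79 transposon families, which were tested together with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are homozygotes against FM7 controls, as fitted by edgeR. A prior count of 2 was used only for log CPM values, in the list tests, principal components and correlations of replicates. CPM values use TMM-scaled library sizes. Each SE is the size of the unshrunken log2 fold change divided by the square root of its quasi-likelihood F statistic. Intervals of fitted folds use this SE, which can be smaller than counting error alone. The procedure was tested on simulated data. Changed genes were drawn from those with a mean of at least 1 CPM, with equal numbers in each direction. Spread followed the fitted trend without differences between single genes. The rates may therefore not hold for the real counts, least of all near the floor. On counts drawn from the means and totals of these libraries, with 200 changed genes among 9312 tested, the test called 37 of 50 genes changed 1.5-fold, 47 of 50 changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 8-fold, and 7 of 9112 unchanged genes.

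Before the data were examined, 23 lists of genes and transposon families were fixed, of which 451 of 457 entries were found in the table, 11 of them through a synonym. The 19 lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1, two-sided, at a preset correlation of 0.01, with adjustment over the 19 lists. No list that passed did so with a correlation estimated from the data, and both values are given. The fry test asks whether a list's genes move, on balance, one way, and its adjusted p is given for the 4 lists that passed by fry and not by camera. It does not compare a list with other genes, so an offset from scaling counts as movement. The named genes followed a rule, also fixed before: flam, DIP1, tj and piwi, then the 12 highest and 12 lowest called genes with at least 1 CPM in the higher group and no overlap between groups, up to 4 members with the smallest adjusted p of each list with both directions shown, and up to 8 transposon families in each direction. Genes outside it are marked as chosen after their values were seen. A gene without control counts is given as a lower bound, against a floor of 3 counts over the control group. A named gene with 1 to 3 control counts in total is given as a ratio of counts per library total, with an exact Clopper-Pearson 95% interval. The share of called genes on the X chromosome was tested by Fisher's exact test, two-sided.

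The alternatives were RLE, upper quartile and no scaling factors, TMM factors from autosomal genes, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 1 CPM in all libraries of a group, a minimum fold change of 1.5 (glmTreat), the replicate number as a block, and leaving out each library in turn. Counting sets of genes with identical counts once was added after the data were seen.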

Results

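Ovarian mRNA was compared between females homozygous for a deletion of the flam promoter and females carrying that deletion over the FM7 balancer, with 3 libraries each. The series concerns the transcription factor Traffic jam and the somatic piRNA pathway, and this comparison asks how ovaries homozygous for the promoter deletion differ from those with 1 copy of it. Library totals were 22996267, 23159557 and 23107127 counts in homozygotes 1 to 3 and 23181058, 19564819 and 21512894 in controls 1 to 3. The first principal component, with 68.8% of the variance, separated the genotypes. The second, with 12.8%, set FM7 replicate 2 apart.

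flam (FBgn0267704) RNA was lower in the homozygotes, at 0.506 ± 0.255 CPM (SD, n = 3) against 1.94 ± 0.0267 CPM (SD, n = 3) in the controls. Its log2 fold change was -1.93 (SE 0.39), with an adjusted p of 0.0119 by edgeR's quasi-likelihood test. flam lies on the plus strand of X from 21631891 to 21790731 and is annotated as a noncoding RNA. DIP1 (FBgn0024807), the gene on its promoter side (X, 21624796 to 21630148, minus strand), was lower by less, with a log2 fold change of -0.40 (SE 0.12, adjusted p = 0.0472). The DIP1 call was lost without homozygous replicate 1, 2 or 3 or FM7 replicate 1, with adjusted p up to 0.143 without homozygous replicate 3. traffic jam (tj, FBgn0000964, 2L, 19464267 to 19467758), which encodes a Maf transcription factor of the gonad soma, fell from 112 ± 9.86 to 61.2 ± 4.76 CPM (SD, n = 3), a log2 fold change of -0.87 (SE 0.08, adjusted p = 5.5e-04). piwi (FBgn0004872, 2L, 10982205 to 10987420), which encodes the Argonaute protein that binds these piRNAs, was not past the threshold (log2 fold change 0.14, adjusted p = 0.098). The list of flam and DIP1 therefore had 2 of 2 members lower, also when adjusted over the list alone. Of 31 other tested genes starting within 500 kb of flam, all at lower positions than flam, 4 were higher and 2 lower, also when adjusted over the list alone. These shares are near those of all 9150 tested genes, of which 1071 were higher and 709 lower. Apart from DIP1 and lncRNA:CR45500, the called genes of this window were chosen after their values were seen. The proteasome gene Rpt6 was lower (log2 fold change -0.24), and CG1801, which overlaps Rpt6 on the other strand (1.10), Abca3 (0.43), fliI (0.19) and lncRNA:CR45500 were higher. lncRNA:CR45500 had 251 counts in homozygotes and 1 in controls, a ratio of 233 (exact 95% interval 41.4 to 9234).

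**Figure D1:**
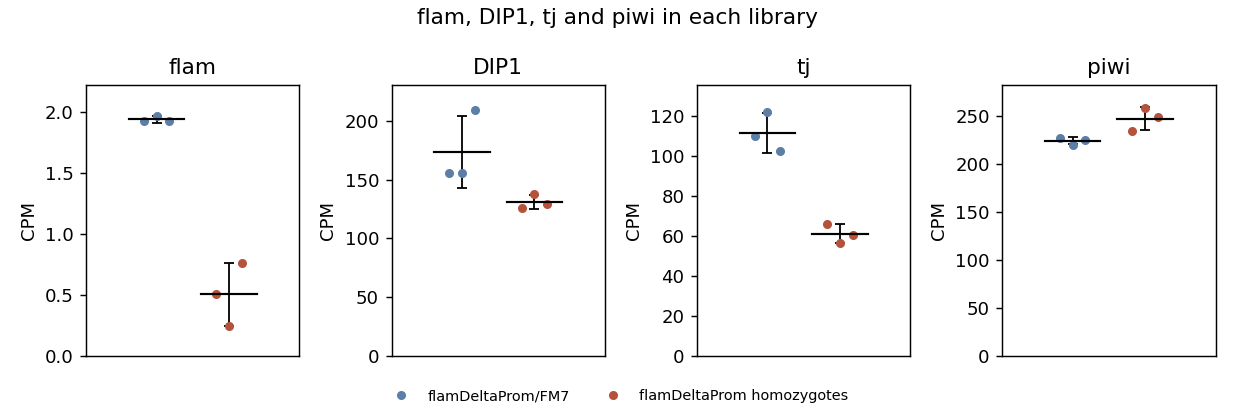
Normalised counts of flam, DIP1, tj and piwi in CPM, on axes that start at 0, in the 3 libraries of each genotype (points), with the mean (line) and SD (error bar). The homozygous libraries lie below the controls for flam, DIP1 and tj, and above them for piwi, whose difference was not past the threshold.

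Transposon RNA was far more abundant in the homozygotes, mainly from long terminal repeat families of the Gypsy class. Of 79 families tested, 32 were higher, 29 of them by at least 2-fold, and 3 were lower. The Gypsy class had 23 of 35 families higher and 1 lower, the other LTR classes 5 of 11 higher and 2 lower, LINE elements 3 of 22 higher, and DNA transposons 1 of 11 higher. The share of all counts that fell on transposons was 0.922% ± 0.169 (SD, n = 3) in homozygotes and 0.159% ± 0.0304 in controls. For Gypsy-class families it was 0.626% ± 0.148 against 0.0276% ± 0.00216, a ratio of 22.7. For both shares the exact permutation p, two-sided, was 0.1, the smallest that 3 against 3 samples can give.

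Most of the largest changes were of families that had almost no RNA in controls. Tabor reached 184 ± 46.0 CPM from 0.227 ± 0.118 (log2 fold change 9.64, SE 0.40, adjusted p = 2.2e-04). The gypsy family, an endogenous retrovirus of follicle cells, reached 1192 ± 480 from 2.66 ± 0.421 CPM (8.80, SE 0.43). mdg1 reached 316 ± 11.4 from 2.72 ± 0.477 CPM (6.87, SE 0.10). Stalker (6.17), gypsy6 (6.05), Stalker4 (5.71) and HMS-Beagle2 (4.73) were also among the 8 largest of families detected in controls, as was a Gypsy-class family that controls did express, at 710 ± 143 against 16.5 ± 7.06 CPM (5.43). The gypsy6 call was lost without FM7 replicate 1, 2 or 3, with adjusted p up to 0.104 without FM7 replicate 2. Of the summed gains in CPM of tested families, copia, springer, gypsy, gypsy1 and blood made up 80.1%, and of these copia, springer and gypsy1 were chosen after their values were seen. The lower families were GATE (log2 fold change -1.07), rover (-1.04) and Max-element (-0.63). GATE was not past the threshold in any of the fits without 1 library, with adjusted p up to 0.0787 without homozygous replicate 3.

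Families reported from follicle cells had 15 of 21 higher and 1 lower, or 16 and 1 adjusted over the list alone, with a median log2 fold change of 2.75. The list was higher than other genes (camera adjusted p = 2.5e-09, and adjusted p = 0.300 with an estimated correlation). Families reported from germ cells had 7 of 22 higher and 1 lower, or 9 and 2 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 1.1e-04, and adjusted p = 0.300 with an estimated correlation). Without homozygous replicate 1 or 2, 2 of these were lower. They included blood (3.91), which both lists hold, invader1 (3.38) and the LINE F-element (1.43). Not every follicle cell family rose. ZAM had 13 counts in all homozygous and 15 in all control libraries and was not tested, and Idefix had a log2 fold change of 0.11 (SE 0.31). The DNA transposon transib1 had 0 counts in controls and 47 in homozygotes, at least 14.5-fold higher against a floor of 3 counts over the control group. ZAM, Idefix and transib1 were chosen after their values were seen.

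**Figure D2:**
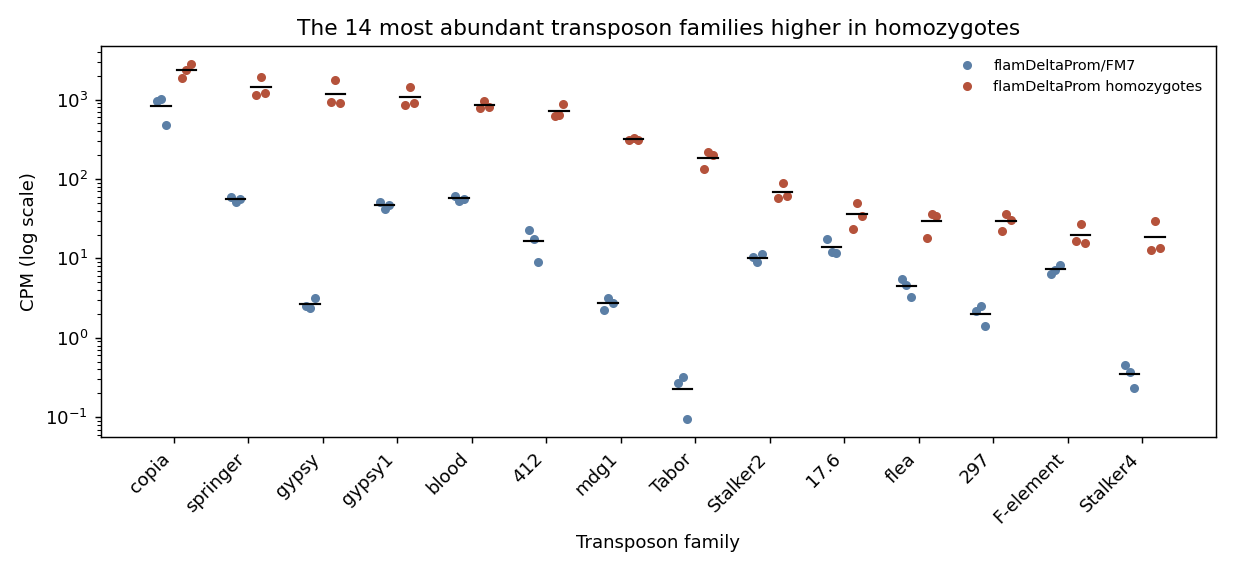
Normalised counts in CPM (log axis) of the 14 most abundant transposon families called higher and detected in controls, in 3 libraries of each genotype (points) with the mean (line). In all 14 families the homozygous libraries lie above the control libraries.

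Among genes, 1071 were higher and 709 lower in homozygotes, and 7370 were not past the threshold. Of these, 644 were higher and 128 lower by at least 2-fold. The values of the groups did not overlap for 41.7% of tested genes, against 10% by chance. The counts rested in part on single libraries: without homozygous replicate 3 the test called 522 genes higher and 225 lower, and without FM7 replicate 1 it called 547 higher and 286 lower. The lower count was also 314 without homozygous replicate 2 and 425 without FM7 replicate 2. By at least 2-fold, 382 were higher without homozygous replicate 3 and 387 without FM7 replicate 1, and 83, 67, 78, 80 and 82 were lower without homozygous replicates 2 and 3 and FM7 replicates 1, 2 and 3 in turn. With library sizes alone, 82.8% of calls were higher, against 60.2% with TMM.

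The genes with the largest rises were nearly silent in control ovaries. CG15278 (2L) had 0 control counts and was at least 34-fold higher against a floor of 3 counts over the group. CG31219 (3R, log2 fold change 7.10), nompC, a mechanosensory channel gene (2L, 6.76), hkb, a gap-type transcription factor gene, and its neighbour CG1090 (3R, 6.39 and 5.72) and the antibacterial peptide gene AttC (2R, 5.93) were among them. Others had 1 to 3 control counts: the ratio of homozygotes to controls was 293 for lncRNA:CR46206 (2L, exact 95% interval 52.2 to 11616), 97.4 for CG31220, next to CG31219 (17.1 to 3884), and 95.2 for CG44422 (X, 32.3 to 464). CG10332 and IM18 overlap on 1 strand and have identical counts, with a ratio of 90.9 (15.9 to 3627). CG31219 reached 24.9 ± 4.19 CPM from 0.18 ± 0.0863 (SD, n = 3, adjusted p = 2.3e-06). AttC varied widely, at 6.18 ± 7.54 CPM, and its call was lost without homozygous replicate 3 or FM7 replicate 1, 2 or 3, with adjusted p up to 0.143 without FM7 replicate 2. The largest fall was of white (w), a marker gene on X for which the groups may carry different alleles, at 1.07 ± 0.273 against 28.2 ± 2.58 CPM (log2 fold change -4.72, SE 0.17). It was followed by Muc4B (-3.20), CG15571 (-3.09), Skel (-3.04), lncRNA:CR45156 (-2.71), CG30334 (-2.58), Femcoat (-2.54), CG4009 (-2.50), CG16956 (-2.49), CG9095 (-2.47), CG15418 (-2.45) and CG11381 (-2.41). Of these 12, w, CG30334, CG9095 and CG15418 were called in all 6 fits without 1 library. The other 8 were lost without homozygous replicate 3, with adjusted p up to 0.155 for Femcoat, and all of them but Skel and lncRNA:CR45156 also without FM7 replicate 1, 2 or 3, and CG11381, CG4009 and Muc4B without homozygous replicate 2.

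Yolk and eggshell genes were lower in the homozygotes. Of 12 yolk and vitelline membrane genes, 11 were lower, also when adjusted over the list alone, with a median log2 fold change of -1.11. The vitelline membrane genes Vm26Ab (-1.32, SE 0.17), Vm26Ac (-1.26, SE 0.13) and Vm34Ca (-1.21, SE 0.14) and the yolk protein gene Yp2 (-1.05, SE 0.13) were among them, and Yp2 went from 4791 ± 240 to 2309.6 ± 398 CPM (SD, n = 3). The list differed from other genes (camera adjusted p = 1.0e-07, and adjusted p = 0.300 with an estimated correlation). Chorion genes, which are expressed late in egg formation, had a median of -1.91, but 1 of 11 was past the threshold, Muc4B, also when adjusted over the list alone. Cp38 was at 1647 ± 1272 in homozygotes and 7386 ± 576 CPM in controls (log2 fold change -2.17, adjusted p = 0.0733), so the spread between homozygous libraries was large. The chorion list was lower than other genes (camera adjusted p = 1.3e-04, and adjusted p = 0.300 with an estimated correlation). The count of lower chorion genes was 6 without homozygous replicate 1, 4 without homozygous replicate 2 and 0 by edgeR without homozygous replicate 3 or FM7 replicate 1, 2 or 3, where Muc4B had an adjusted p up to 0.0747. With all libraries 7 of 11 were lower by DESeq2 and by limma-voom, and 0 with the replicate block in edgeR, so the number of chorion calls depends on the tool.

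Follicle cell genes went both ways, with 3 higher and 7 lower of 23, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.401). cas, a transcription factor gene of early follicle cells, was higher (log2 fold change 2.27, SE 0.18), whereas wbl (-1.12), tj (-0.87) and Cad99C (-0.79) were lower. Without homozygous replicate 3 or FM7 replicate 1, 4 follicle cell genes were lower. Ecdysone genes had 1 higher and 5 lower of 20, the same adjusted over the list alone. Blimp-1 was higher (1.69), and Hr3 (-1.07), spo (-0.78) and br (-0.67) were lower. That list's camera adjusted p of 0.0441, or adjusted p = 0.300 with an estimated correlation, was 0.0816 without homozygous replicate 1 and 0.0862 without FM7 replicate 2. Without homozygous replicate 1, 2 or 3 or FM7 replicate 3, 3 members were lower, and without homozygous replicate 1, 2 were higher. The Blimp-1 call was lost without homozygous replicate 3 or FM7 replicate 1 or 3 and that of Hr3 without homozygous replicate 3, with adjusted p up to 0.0824 and 0.0559. Germline and oocyte genes had 1 higher and 2 lower of 29, none adjusted over the list alone in either direction, and a median of -0.02, of opposite sign to the mean of 0.02 (camera adjusted p = 0.854). stet (0.19) was higher and me31B (-0.26) and pgc (-0.25) were lower, and all of these calls were lost without homozygous replicate 2 or 3 or FM7 replicate 1 or 2, with adjusted p up to 0.144 for me31B without homozygous replicate 3. Without homozygous replicate 1, 3 germline genes were higher and 0 lower by edgeR, and without FM7 replicate 3, 4 were higher. With all libraries the counts were 6 higher and 0 lower by edgeR with library sizes alone, 2 and 0 with upper quartile scaling, 0 and 0 with the replicate block, and 3 and 4 by DESeq2.

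Immune genes were higher in homozygotes. Antimicrobial peptide and immune recognition genes had 14 of 25 higher and none lower, or 18 higher and 1 lower adjusted over the list alone, with a median log2 fold change of 2.0. Of the 25 tested members, 3 had at least 10 CPM in control ovaries, so most started from low levels. The recognition receptor gene PGRP-SA (3.38, SE 0.37), the serpin gene nec (2.05, SE 0.30) and the NF-kappaB genes Dif (1.10, SE 0.18) and Rel (0.35, SE 0.06) had the smallest adjusted p. The list was higher than other genes (camera adjusted p = 1.8e-06, and adjusted p = 0.143 with an estimated correlation), and 9 members were higher without homozygous replicate 3 or FM7 replicate 1. JAK/STAT and humoral stress genes had 5 of 11 higher, or 7 adjusted over the list alone. They were led by TotM (5.29), TotA (4.54), the cytokine gene upd3 (2.12) and its feedback inhibitor gene Socs36E (1.11), with a camera adjusted p of 1.3e-04 and adjusted p = 0.143 with an estimated correlation. Without FM7 replicate 1, 3 members of this list were higher, and TotA had an adjusted p of 0.073. In the list of siRNA pathway and antiviral genes, vir-1 (1.31), Srg3 (1.92) and Vago (3.01) were higher of 10 tested, or 4 adjusted over the list alone (camera adjusted p = 0.12, and 0.0355 without FM7 replicate 2, fry adjusted p = 0.0354, higher). vir-1 had an adjusted p of 0.0502 without FM7 replicate 1.

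Haemocyte markers moved with these genes. Of 13 haemocyte genes, 8 were higher and 1 lower, or 10 and 1 adjusted over the list alone, with a median log2 fold change of 3.11. The prophenoloxidase genes PPO1 (3.11, SE 0.29) and PPO2 (3.23, SE 0.30) and the peroxidasin gene Pxn (3.14, SE 0.26) were higher, and Pxn reached 29.4 ± 8.72 from 3.34 ± 0.648 CPM (SD, n = 3). srp, a GATA factor gene, was lower (-1.21, SE 0.10), and without FM7 replicate 3 it was 1 of 3 lower members. The list had a camera adjusted p of 3.8e-04, and adjusted p = 0.300 with an estimated correlation. Of its tested members, 6 had at least 10 CPM in control ovaries. Fat body genes had 2 of 10 higher, fit (5.24) and FASN1 (0.64), or 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.428, fry adjusted p = 0.0156, higher), and FASN1 had an adjusted p of 0.0807 without FM7 replicate 3. Without FM7 replicate 1 or 3, 1 fat body gene was higher, and without homozygous replicate 2, 5 were. Muscle sheath genes had 11 of 20 higher, or 16 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 4.4e-06, and adjusted p = 0.341 with an estimated correlation). Obsc (1.09), Mp20 (0.95), Msp300 (0.77) and Prm (0.61) led this list. The number of muscle calls changed with the library left out: none was past the threshold by edgeR without FM7 replicate 1, 1 without FM7 replicate 3, 3 without homozygous replicate 2 and 5 without homozygous replicate 3. These fits hold fewer samples, and the list median stayed positive, from 0.57 without homozygous replicate 3 to 0.91 without FM7 replicate 2.

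Heat shock and detoxification genes were also higher as lists in the homozygotes, in which haemocyte markers had a median log2 fold change of 3.11. Of detoxification genes, 27 of 40 were not past the threshold. JNK, apoptosis and DNA damage genes went both ways, with a median of 0.09. Heat shock and chaperone genes had 14 higher and 2 lower of 22, the same adjusted over the list alone, with a median log2 fold change of 1.46. stv (1.76, SE 0.16), Hsp70Aa (1.72, SE 0.13) and Hsp70Ab (1.66, SE 0.13) were higher, the last pair being near-identical copies that may share reads, and Hsp27 was lower (-0.33). The list had a camera adjusted p of 1.3e-04, and adjusted p = 0.300 with an estimated correlation. Without homozygous replicate 3 or FM7 replicate 1, 9 members were higher, and Hsp27 had an adjusted p of 0.0868 without homozygous replicate 3. The count of lower members was 0 by edgeR without homozygous replicate 1 or 3, 1 without FM7 replicate 1 or 2 and 4 without FM7 replicate 3. Detoxification and oxidative stress genes had 12 higher and 1 lower of 40, or 14 and 1 adjusted over the list alone. The glutathione transferase genes GstD5 (2.79) and GstD2 (2.14) and the cytochrome P450 gene Cyp6a13 (0.73) were higher and Sod3 (-0.76) lower. That list had a camera adjusted p of 0.00118, and adjusted p = 0.300 with an estimated correlation, and 7 members were higher without homozygous replicate 3 or FM7 replicate 1, and 6 lower without FM7 replicate 3. JNK, apoptosis and DNA damage genes had 8 higher and 3 lower of 26, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.174, fry adjusted p = 0.00332, higher). The cell death gene rpr (1.89), the matrix protease gene Mmp1 (1.21) and Xrp1 (1.09) were higher and RnrL, a ribonucleotide reductase gene, was lower (-0.45). Without homozygous replicate 3, 4 members were higher and 1 lower, and without homozygous replicate 2 or FM7 replicate 1, 5 were higher and 1 lower.

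Somatic piRNA pathway genes had 3 lower of 23, tj (-0.87), nxf2 (-0.33) and mael (-0.21), or 2 adjusted over the list alone. Their camera adjusted p was 0.0856, and 0.0294 without FM7 replicate 2, and the fry test placed them lower (adjusted p = 0.0129). Their median was -0.09, whereas the median of all genes was -0.009 with TMM and 0.073 with library sizes alone. A shift of this size may therefore rest on scaling, and with library sizes alone 1 member was higher and 2 lower. The mael call was lost in the fits without any library but FM7 replicate 2, with adjusted p up to 0.148 without homozygous replicate 2, and 5 members were lower without FM7 replicate 3. Germline pathway genes had 4 higher and 1 lower of 19, the same adjusted over the list alone (camera adjusted p = 0.428). qin (0.43), krimp (0.28) and aub (0.22) were higher and moon (-0.65) lower. Without homozygous replicate 3, 1 was higher, and without any other library 2 were. With all libraries 2 were higher by limma-voom, and by edgeR 2 without a filter, 2 with the replicate block and 0 with a minimum fold of 1.5. aub was past the threshold in none of these 6 fits, with adjusted p up to 0.16 without homozygous replicate 2, and krimp had 0.0559 without homozygous replicate 3.

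Of the remaining tissue markers few were detected. Nervous system genes had 1 of 4 tested higher, also adjusted over the list alone, Snap25 (log2 fold change 2.84). That call was lost without homozygous replicate 2 or 3 or FM7 replicate 1, with adjusted p up to 0.0779 without homozygous replicate 3, and 2 were higher without FM7 replicate 3. Spermatheca and oviduct genes had 1 of 5 lower, also adjusted over the list alone, Glut4EF (-0.72, camera adjusted p = 0.401), or 2 without homozygous replicate 1. Their median of -0.07 and mean of 0.03 differed in sign. Of digestive tract genes, 4 were tested and none was past the threshold, with or without adjustment over the list alone. betaTry was at 7.04 ± 12.1 in controls and 0.744 ± 0.327 CPM in homozygotes (SD, n = 3). FM7 replicate 2, which also lay apart on the second principal component, decided these values. Without it all 4 were higher in homozygotes on the log2 scale, and betaTry (3.86, adjusted p = 0.0159), Amy-p (4.34, adjusted p = 0.0141) and Amy-d (2.69, adjusted p = 0.0273) were past the threshold, as was 1 list member not tested with all libraries. Without homozygous replicate 1 or FM7 replicate 3, 1 digestive tract gene was higher.

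**Figure D3:**
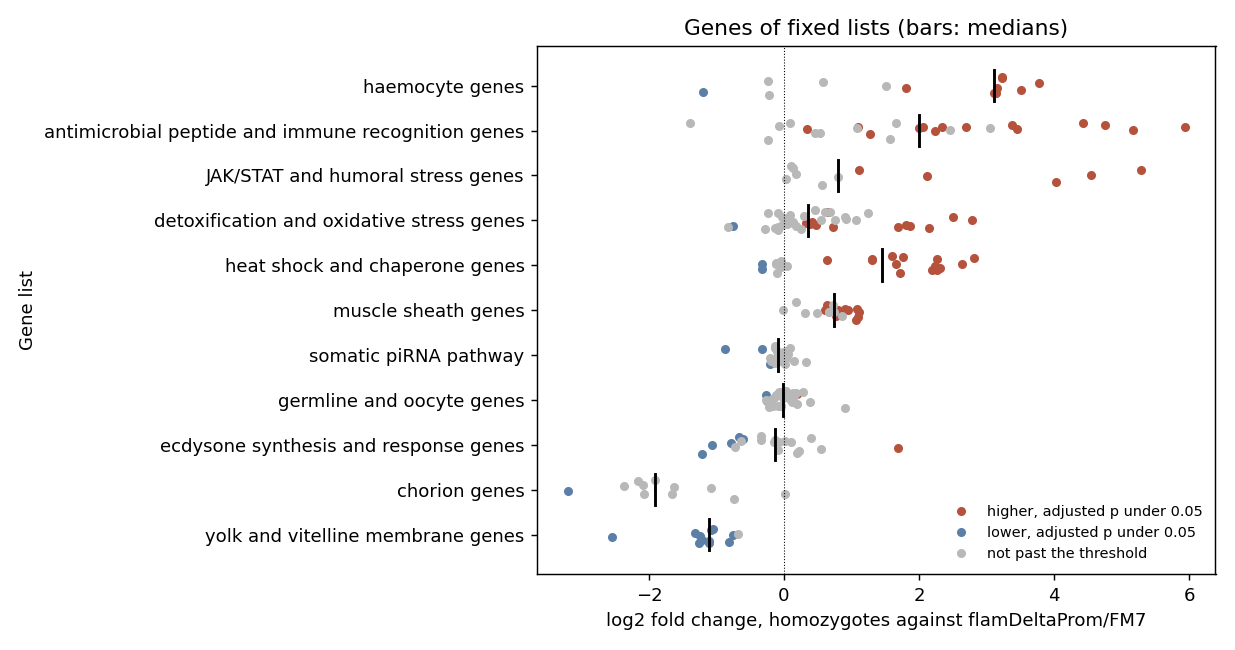
Log2 fold changes of homozygotes against FM7 controls for the tested genes of 11 fixed lists, each point a gene, coloured by the edgeR call, with the list median as a bar. Yolk, vitelline membrane and chorion medians lie below 0, at -1.11 and -1.91, and the haemocyte median lies at 3.11.

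The groups also differ over the whole X chromosome, since the controls carry FM7. Among tested genes, 327 of 1605 on X (20.4%) and 1449 of 7514 on the autosomes (19.3%) were called. The odds ratio was 1.07 (95% interval 0.933 to 1.23, p = 0.314, Fisher's exact test), so no difference was detectable at these numbers. By the same exact test it was 1.25 (p = 0.0165) without FM7 replicate 1, 1.21 (p = 0.0264) without homozygous replicate 2 and 1.18 (p = 0.016) without FM7 replicate 3, and 0.855 (p = 0.138) for calls of at least 2-fold. Split by direction, the odds ratio was 1.21 for being higher and 0.751 for being higher by at least 2-fold, each with p = 0.0584 by Fisher's exact test after adjustment over 5 such tests, and neither was past the threshold. Of the genes mutated on FM7 balancers, 2 of 4 tested were lower, w and y (log2 fold change -1.57), or 3 adjusted over the list alone. Less RNA from FM7 copies would make such genes higher, not lower, in homozygotes. The falls of w and y cannot be told apart from alleles carried on the deletion-bearing X. sn and g had -0.13 each and were not past the threshold. The y call was lost without homozygous replicate 1 or 2 or FM7 replicate 1 or 2, with adjusted p up to 0.0801 without homozygous replicate 2, 3 of these markers were lower without FM7 replicate 3, and 1 was higher without homozygous replicate 2.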

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

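Counting identical sets of genes once was chosen after seeing the data and moved no count by over 1.5 times. flam stayed lower and past the threshold in each alternative, with log2 fold changes of -2.34 to -1.61 without 1 library. The transposon counts without 1 library were 25 to 33 higher and 2 to 3 lower, and across other settings the one count that changed by over 1.5 times was that of lower families, of which 1 passed a minimum fold of 1.5. That minimum left 355 genes higher and 63 lower, and 351 and 57 by at least 2-fold, as a stricter hypothesis must. With library sizes alone 320 genes were lower, and 1391 of the 1780 called genes were still called. That setting also called 5 siRNA pathway and antiviral genes and 5 follicle cell genes higher, and 1 gene of the JNK, apoptosis and DNA damage list lower. Upper quartile scaling gave 69.0% of calls higher, and no scaling moved the median of all genes by over 0.1 on the log2 scale. Without 1 library the test called 522 to 976 genes higher and 225 to 853 lower, and 382 to 683 and 67 to 153 by at least 2-fold. These fits hold fewer samples, yet the 853 lower genes without FM7 replicate 3 exceeded the 709 with all libraries. With estimated correlations 0 lists were higher and 0 lower, against 8 and 3, and without a filter 5 were lower. Without 1 library 8 to 10 lists were higher and 2 to 4 lower.

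The X odds ratio was 0.855 for calls of at least 2-fold and ran from 1.05 to 1.25 without 1 library. The germline list changed side with library sizes alone (adjusted p = 0.992) and in 2 fits without 1 library (0.412 to 0.959 over these fits), and the fat body list without a filter (0.921), none past the threshold. Hr39 had a log2 fold change of 0.013 with library sizes alone. With limma-voom Amy-d had 0.63, Amy-p 2.23 and betaTry 0.78. Without 1 library Amy-d ran from -2.35 to 2.69, Amy-p from -1.27 to 4.34, alphaTry from -4.0 to 2.93 and betaTry from -3.81 to 3.86, each positive without FM7 replicate 2. The cause of these shifts was not tested, except that the digestive genes turned with FM7 replicate 2.

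No pairing of the samples by replicate number was seen. The deviations of same-numbered samples had correlations of -0.303, -0.071 and -0.0387, and no sample correlated best with its own number. With 3 samples per group, a modest shared batch could be missed. The replicate block gave 674 genes higher and 347 lower, 76 lower by at least 2-fold, an X odds ratio of 1.22 (Fisher's exact p = 0.0163), and log2 fold changes of 0.31 for Amy-d and 1.19 for Amy-p. Of 96 named genes and families called with all libraries, flam not counted, 66 stayed called in all 6 fits without 1 library. Of other results under alternatives, lists stayed on the same side and direction in 185, became weaker in 13, passed in 7 and changed side in 4, and named genes and families in 1757, 179, 26 and 10. Depth limits genes below about 0.129 to 0.153 CPM in a library, by unscaled totals.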

Other observations

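The tests of other sample splits, X-linked alleles, transposon insertions and neighbouring genes were set before their results were seen, whereas those on haemocytes, yolk genes, transposon dosage and shared reads, the check of gene length and the comparisons of insertions other than that of the families that rose were chosen afterwards. Genes that rose by at least 2-fold often lay side by side. The hypothesis that single loci respond as units was tested by counting neighbouring pairs, of which 127 had both members higher by at least 2-fold. In 10000 shuffles within chromosomes the median was 45 pairs (95% interval 33 to 58), and the permutation p of 0.0001 is the smallest they can give. The pairs, chosen after their values were seen, included families of related genes, such as NimB4 and NimB5, TotA and TotC, and Gr64d and Gr64e, whose members may respond alike or share reads, so the excess does not separate a local effect from shared regulation of a gene family. Other pairs were hkb with CG1090, and TotM with fusl.

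The hypothesis that insertions of the risen transposon families alter nearby genes may apply to part of the genes higher by at least 2-fold. Of these, 9.05% lay within 5 kb of a reference insertion of such a family, against 6.10% of genes not called (odds ratio 1.53, 95% interval 1.13 to 2.05, Fisher's exact test, adjusted p = 0.0236 over 6 tests). This is weak evidence, since families that were not called gave 1.25 (0.943 to 1.63), a value inside that interval. With gene length and both kinds of insertion in a logistic model, the odds ratio was 1.35 (95% interval 1.002 to 1.83). Among the 41 genes higher by at least 16-fold the risen families gave 0.789 (0.092 to 3.07) and the families not called 2.95 (1.24 to 6.37). In a comparison not set before, 10.9% of genes lower by at least 2-fold lay near risen families. Their odds ratio was 1.89 (0.993 to 3.34, Fisher's exact test, adjusted p = 0.0767). The nearness is therefore not shown to be particular to genes that rose. Insertions in these stocks that the reference lacks were not examined. FM7 and the deletion-bearing X are different chromosomes. Whether their alleles account for calls on X could not be told from the share of called genes there. Its odds ratio of 1.07 had an interval from 0.933 to 1.23, which includes 1.

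Haemocyte genes rose with immune genes. Fewer late egg chambers would raise the genes of every other cell type alike. Of all 13 tested haemocyte genes, 5 had an interval of the fold, adjusted over the 13, above the highest of 20 muscle sheath genes (log2 fold change 1.11). The error of that muscle gene was not counted. With all libraries this met the rule for this test, which was written after values were seen. Members of the list moved together (estimated correlation 0.41), so the 5 genes are not independent. There were 3 such genes without FM7 replicate 1 and 2 without FM7 replicate 3, fewer than the rule required, so the result rests on single libraries. The test therefore cannot argue against fewer late egg chambers. Of the 4 comparisons with muscle that were tried, 1 used only haemocyte genes that rose and is left out as selected. Others were less clear, since the medians of the 2 lists differed by 2.37 with a bootstrap interval of -0.22 to 2.50. By edgeR 7 haemocyte and 0 muscle sheath genes passed a minimum fold of 1.5, but 7 and 7 without homozygous replicate 1 and 3 and 0 without FM7 replicate 3. Fewer late egg chambers therefore stay open, as the whole cause or as a part. More haemocytes on or in the dissected ovaries stay open, since no test here is independent of the rise of these genes, and the list's most abundant members, the collagen genes Col4a1 (359 against 421 CPM) and vkg (268 against 316), which control ovaries also express, were not past the threshold. More fat body stays open too (odds ratio 1.89, 0.195 to 9.48), with apolpp at 36.4 against 13.4 CPM and not past the threshold, as does an untested response of ovarian cells to the genotype.

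Yolk and vitelline membrane genes fell. Scaling by a few abundant genes is argued against as the whole cause, since at least 10 of the 11 called yolk and vitelline membrane genes stayed called, and all 11 negative, under RLE, upper quartile, library size and DESeq2. A smaller share of late egg chambers may account for the fall. The germline and oocyte list had a median log2 fold change of -0.0205 (bootstrap interval -0.09 to 0.09), but its members went both ways and germ cells are present at all stages, so this cannot be told apart from lower transcription per follicle cell.

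Insertions carried on the deletion-bearing X and absent from FM7 would give at most a 2-fold rise in homozygotes, which carry 2 such chromosomes against 1. Of the 32 families called higher, 21 had a 95% interval of the fold above 2 and transib1 a lower bound of 14.5. This argues against dosage as the whole cause for these 22 as a set, but not for each of them. The families were chosen by their call, and the intervals were not adjusted over them. The lower limits of micropia, invader4 and Dm88 were 1.04, 1.07 and 1.16 on the log2 scale, where 2-fold is 1. The gypsy6 call was lost without FM7 replicate 1, 2 or 3. For the other 10, among them copia, roo and HeT-A, dosage cannot be told apart. The rise of gypsy1 was 0.866 times that of gypsy, and the ratio of gypsy1 to gypsy went from between 14.9 and 20.7 in controls to between 0.833 and 1.01 in homozygotes, so its rise cannot be told apart from reads of gypsy assigned to it, because read assignment is not known. springer gained 1373 CPM against 1190 for gypsy, but reads assigned away from gypsy would be missing from the count of gypsy, so this sets no limit and the same stays open for springer. The difference that the design names is the deletion of the flam promoter, against controls that carry FM7. Small RNAs were not analysed here, so a loss of flam piRNAs was not measured.

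In a refit of the 10 possible splits of the 6 samples into 3 and 3, the split by genotype called 1780 genes, and the highest of the others 5, so 1 split gave as many. With 10 splits, no share under 5% can be reached.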
